A study of Homo sapiens with 6 samples.

How the data were processed

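RNA from cells of HOS, a human osteosarcoma cell line, was measured by RNA sequencing in 6 libraries: 3 of cells treated for 24 h with Agrimol B, a polyphenol of the agrimony plant, and 3 of control cells. The labels list no treatment for the control cells and do not say whether they received the solvent, and the dose of Agrimol B is not given in the sources used here. Libraries were made with a stranded mRNA kit, per the labels' protocols. The labels do not say that the replicates came from separate cultures. The p-values therefore set the group difference against the spread between these libraries, which may be only technical.

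The authors deposited 1 table of FPKM values (fragments scaled to transcript length and to the mapped fragments of the library) with 1 column per library. The submitters' processing notes name FastQC, cutadapt, Trimmomatic, HISAT and the genome build hg38, with no versions or roles. The program that computed the FPKM values, its annotation, its use of strand and any filter on genes are not given in the sources used here. The columns of the Agrimol B libraries carry the names in those samples' descriptions. The columns of the control libraries carry the same letters as those descriptions in the other order, with the same number, and were matched on that basis. The table held 16376 genes by symbol, none of them at 0 in every library, and 4.88% of its values were 0. Of these genes, 16262 were matched to GENCODE release 29, from which coordinates on hg38 (GRCh38) were taken, and 99.72% of those matched were protein-coding. The table held 0 mitochondrially encoded genes.

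FPKM values hide the number of reads. In genes with very few reads the values of 2 libraries stand in a ratio set by their depths, so ratios of genes under 0.05 FPKM in both libraries were examined in all 15 pairs of libraries. In each pair 5.0% to 10.8% of 266 to 405 such genes lay within 0.01 (log2) of 1 common ratio, and the 15 ratios fitted 1 depth per library to within 0.009 (log2). Relative to the first control library, the depths were 0.99 and 1.04 for the other control libraries and 1.01, 1.19 and 1.16 for the Agrimol B libraries. The total number of reads, and so the counting error of a single value, remains unknown. Total FPKM per library lay between 352990 and 359537.

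Values were analysed as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 6 libraries entered the tests, which left 12143. Differences were tested with limma 3.58.1 in R 4.3.3 (a linear model with a group term, then empirical Bayes moderation with a variance trend, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of adjusted p 0.05. A log2 difference on this scale understates the change of genes with low values. A fold in the text is instead the ratio of the group means of FPKM. The count of genes changed at least 2-fold required an absolute log2 difference of at least 1. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.

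The 36 gene lists were fixed before the data were examined. They held 946 genes, of which 913 were in the table (62 under an older symbol) and 804 were tested. The 34 lists with at least 5 tested members were tested with camera, in limma, with a preset correlation between genes of 0.01, which asks whether the members of a list rank higher or lower than the other genes. The adjusted p was computed over these lists. Camera with a correlation estimated from the residuals and fry, which asks whether the members move on balance in 1 direction and compares them with no other genes, were run beside it. Counts of members that rose or fell use the adjusted p over all genes tested, and counts adjusted over the list alone are given with them. The genes named were set by a rule fixed at the same time: the 12 largest rises and the 12 largest falls among changed genes whose 3 Agrimol B values lay on 1 side of the 3 control values, and up to 3 changed members of each list with the largest differences. This gave 117 genes, of which 1 is not reported here. Genes named outside the rule are marked as chosen after their values were seen.

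The steps were tested on simulated libraries of the same design, drawn from normal distributions around each gene's mean over the 6 libraries. The spread was each gene's residual variance after limma's moderation, so the simulation follows the model of the test itself. It held 12072 tested genes, of which 100 were changed 2-fold and 100 were changed 1.5-fold. Genes with the lowest values were not among those changed. Of these, 89% and 74% were recovered. The genes of 1 further list were raised by less than 1.5-fold, and that list was called (camera adjusted p = 1.92e-35). Of 191 genes called, members of that list included, 14 were false (7.33%, above the nominal 5%), and 0 of 50 unshifted lists were called. In the real libraries 6311 of 12143 genes were called, a far larger share than was changed here, so these rates do not carry over to them. The simulated genes were drawn independently, so the simulation does not test lists of correlated genes. In the real libraries, the 9 splits that mix the groups, each of which keeps part of the group difference, gave 7 to 15 shifted lists with at most 1 gene called. Alternatives were another pseudocount, no filter and a higher filter, median-ratio scaling and quantile normalization, no variance trend, the replicate number as a block, and each library left out in turn. Removal of trends with transcript length and GC content, and removal of genes with scattered replicates or read-through transcription, were added after the data were seen.

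Genes that share sequence with near-identical copies or overlap another gene are uncertain, since reads can be divided between them in a way that is not given. Of the 117 named genes, 35 overlapped another annotated gene on the same strand and 52 on the opposite strand, 68 in all. The opposite-strand overlaps matter if strand was not used in the authors' quantification.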

Results

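HOS is a cell line established from a human osteosarcoma, a bone tumour. Agrimol B is a phloroglucinol derivative from plants of the genus Agrimonia. The study asked which transcripts differed between HOS cells after 24 h with Agrimol B and control cells, with 3 libraries in each group. Between 11993 and 12134 genes reached 1 FPKM in a library. Libraries of 1 group resembled each other (Pearson r of log2(FPKM + 1) across tested genes 0.9861 to 0.9884) more than libraries of different groups (0.9468 to 0.9504). The first principal component, with 71.4% of the variance, separated the groups, and the second held 8.0%. FPKM values are given throughout as group means ± SD (n = 3 libraries per group). Adjusted p-values of single genes are from limma.

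With Agrimol B, stress-response genes such as TRIB3, SESN2 and DDIT3 were among the largest rises, and actin and matrix genes such as ACTA2 and COL3A1 among the largest falls. On the log2(FPKM + 1) scale the largest rise was that of MMP1, an interstitial collagenase (chromosome 11, 102789920 to 102798160, minus strand), from 3.45 ± 0.231 to 141 ± 20.8 FPKM, or 40.8-fold (adjusted p = 6.74e-06). The largest fall on that scale was that of ACTA2, smooth muscle actin (chromosome 10, 88935074 to 88991339, minus strand), from 99.2 ± 2.54 to 4.76 ± 0.298 FPKM, or 20.9-fold (adjusted p = 2.82e-06). In all, 6311 of 12143 genes changed, 3713 higher and 2598 lower with Agrimol B, and the median log2 difference over all tested genes was 0.07. This excess of rises was absent with median-ratio scaling (3067 higher, 3164 lower) and quantile normalization (3101 higher, 3083 lower). Of the 6311 genes, 491 changed at least 2-fold, 285 higher and 206 lower, against 239 higher and 261 lower with median-ratio scaling and 244 and 262 with quantile normalization. With a pseudocount of 0.1 this number was 833. Most calls were therefore differences of less than 2-fold.

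**Figure D1:**
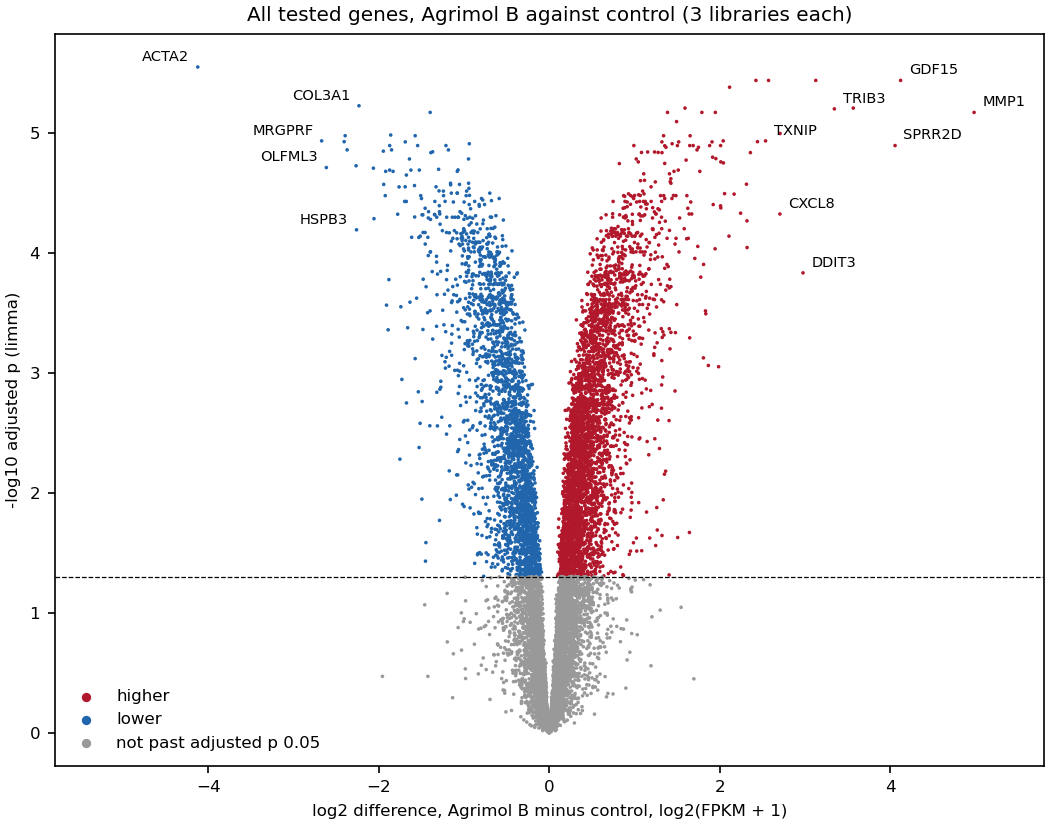
Each point is 1 of 12143 tested genes, with the log2 difference between Agrimol B and control libraries (log2(FPKM + 1)) on the x axis and the negative log10 of limma's adjusted p on the y axis; the dashed line marks adjusted p 0.05. MMP1 lies farthest to the right (4.98) and ACTA2 farthest to the left (-4.12), and 3713 genes were higher and 2598 lower.

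After MMP1, the 12 largest rises included GDF15, a secreted stress-induced cytokine (chromosome 19, 18374731 to 18389176, plus strand), which rose 29.1-fold from 1.40 ± 0.114 to 40.7 ± 2.32 FPKM (adjusted p = 3.65e-06). The stress-induced pseudokinase TRIB3 rose 10.8-fold, the leucine sensor SESN2 11.2-fold, and DDIT3, which encodes the transcription factor CHOP, 8.68-fold. The chemokine CXCL8 rose 10.3-fold, the thioredoxin-binding protein TXNIP 7.25-fold, the secreted peptide precursor VGF 7.09-fold, and the transcription factors CEBPB and CAMTA2 6.18-fold and 5.63-fold. SPRR2D and KLHDC7B were close to 0 in the control libraries (0.158 ± 0.147 and 0.0633 ± 0.0435 FPKM) and stood at 18.2 ± 1.94 and 11.6 ± 0.862 FPKM with Agrimol B. The ratios of their means, 115-fold and 183-fold, exceeded that of MMP1 but rest on control values near 0, and with a pseudocount of 0.1 their log2 differences (6.35 and 6.20) also exceeded that of MMP1 (5.30). SPRR2D belongs to a cluster of near-identical genes, and its value is uncertain for that reason. GDF15, DDIT3 and CAMTA2 overlap another annotated gene on their strand.

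The 12 largest falls also included COL3A1, a fibrillar collagen chain (chromosome 2, 188974320 to 189012746, plus strand), which fell 4.89-fold from 93.0 ± 1.71 to 19.0 ± 0.805 FPKM (adjusted p = 5.94e-06). The secreted olfactomedin-like genes OLFML3 and OLFML2A fell 7.84-fold and 5.58-fold, the stromal surface glycoprotein CD248 6.80-fold, and TINAGL1 4.6-fold. The calcium-binding protein S100A4 fell 5.44-fold from 84.5 ± 6.52 FPKM. MRGPRF fell 9.97-fold, the small heat shock protein HSPB3 9.80-fold, TMEM119 11.4-fold and CCDC85C 5.38-fold. ALPP, the placental alkaline phosphatase, fell 6.44-fold, with the reservation that it has near-identical neighbours. ACTA2 also shares sequence with the other actins, and OLFML3, COL3A1, S100A4 and TINAGL1 overlap another annotated gene on their strand.

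**Figure D2:**
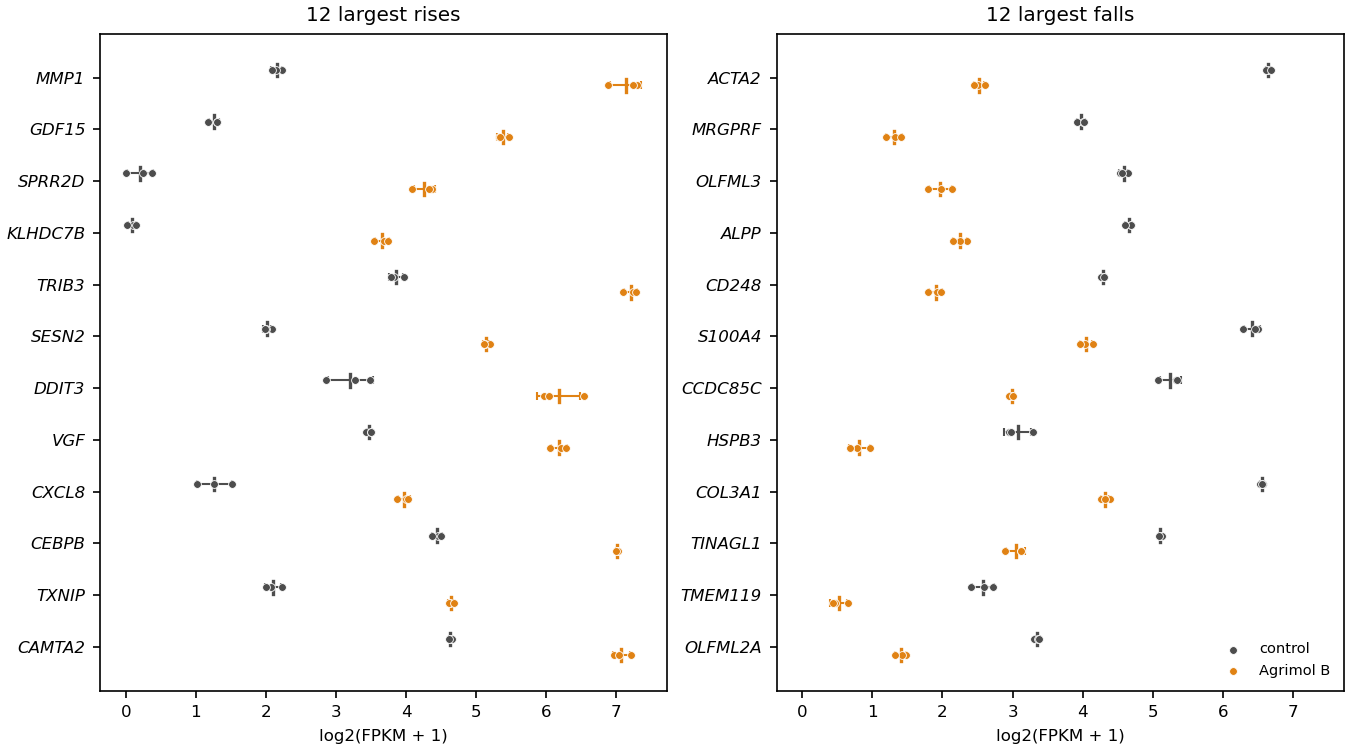
The log2(FPKM + 1) of the 12 largest rises and 12 largest falls is plotted per library, with points for the 3 libraries of each group, a vertical tick for their mean and a horizontal bar for ± 1 SD. In all 24 genes the libraries of the 2 groups do not overlap, which the choice of these genes required.

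To ask whether known gene groups moved, 34 fixed lists were tested. By camera with a preset correlation, 20 lists were shifted. With an estimated correlation 0 lists passed, and the lowest adjusted p was 0.0544, shared by the cell division, heat shock and cholesterol lists. This form of camera also tests each list on the 4 residual degrees of freedom of the libraries. Of those 34 lists, 29 passed by fry. Each list is given with its members that changed. These counts are to be read against the 3713 rises and 2598 falls among all 12143 tested genes.

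Genes induced when translation is slowed by stress rose together. Of 28 tested targets of ATF4 and the integrated stress response, 23 rose and 0 fell (the same numbers adjusted over the list alone), with a median log2 difference of 1.07 (camera adjusted p = 1.16e-09; adjusted p = 0.0651 with an estimated correlation). TRIB3 rose from 13.5 ± 0.983 to 147 ± 9.69 FPKM, SESN2 from 3.06 ± 0.153 to 34.4 ± 1.1 FPKM and DDIT3 from 8.37 ± 2.02 to 72.7 ± 16.5 FPKM. Of 25 chaperones and unfolded protein response genes of the endoplasmic reticulum, 17 rose and 0 fell, also adjusted over the list alone (median 0.64, camera adjusted p = 0.000209; adjusted p = 0.155 with an estimated correlation). The chaperone HSPA5, also called BiP, rose 2.83-fold to 439.6 ± 13.5 FPKM (adjusted p = 8.04e-06), the transcription factor XBP1 4.14-fold and the degradation factor HERPUD1 3.20-fold. Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 12 rose and 0 fell (14 and 1 adjusted over the list alone; median 0.39, camera adjusted p = 0.000884; adjusted p = 0.0714 with an estimated correlation). WARS (WARS1) rose 2.78-fold, SARS (SARS1) 2.00-fold and AARS (AARS1) 1.95-fold.

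Cell division genes fell together. Of 40 genes of G2/M and mitosis, 36 fell and 0 rose, also adjusted over the list alone (median -0.69, camera adjusted p = 1.80e-16; adjusted p = 0.0544 with an estimated correlation). The mitotic kinesin KIF20A fell 3.00-fold from 31.4 ± 2.24 to 10.4 ± 0.474 FPKM (adjusted p = 3.52e-05), DLGAP5 2.65-fold, and the mitotic kinase AURKA 2.16-fold. Of 40 genes of DNA replication and S phase, 32 fell and 0 rose (32 and 2 adjusted over the list alone; median -0.44, camera adjusted p = 1.18e-10; adjusted p = 0.0544 with an estimated correlation). The thymidylate synthase TYMS fell 2.24-fold and the transcription factor E2F2 2.38-fold. Of 25 genes of repair by recombination and the Fanconi pathway, 6 fell and 2 rose (5 and 2 adjusted over the list alone; median -0.16, camera adjusted p = 0.0190; adjusted p = 0.343 with an estimated correlation). This last list lost its call without the third Agrimol B replicate (median -0.11, adjusted p = 0.0564; 0.00734 to 0.0564 over all alternatives run with the preset correlation). The helicase BRIP1 fell 2.31-fold, BARD1 1.63-fold and RMI2 1.53-fold. Of 16 replication-dependent histones, 5 rose and 4 fell, also adjusted over the list alone, with no shift by camera (adjusted p = 0.726). HIST2H2BE (H2BC21) rose 1.98-fold and HIST1H2AG (H2AC11) 2.00-fold, while HIST1H4C (H4C3) fell 1.59-fold, a call lost without control replicate 2 or 3 or without Agrimol B replicate 1 or 3 (adjusted p 0.0804 to 0.122; 0.0302 to 0.122 over all alternatives). Histone genes resemble one another, and most of their transcripts lack the poly(A) tail that mRNA kits select.

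Lipid synthesis genes also fell. Of 24 genes of cholesterol synthesis and uptake, 21 fell and 0 rose, also adjusted over the list alone (median -0.76, camera adjusted p = 3.97e-10; adjusted p = 0.0544 with an estimated correlation). HMGCS1, which makes the precursor of mevalonate, fell 2.26-fold from 113 ± 3.81 to 50.2 ± 1.87 FPKM (adjusted p = 2.63e-05), HSD17B7 2.55-fold and the lanosterol synthase LSS 2.29-fold. Of 18 genes of fatty acid synthesis and desaturation, 11 fell and 2 rose, also adjusted over the list alone (median -0.38, camera adjusted p = 0.000982; adjusted p = 0.0714 with an estimated correlation). The desaturases FADS2 and SCD fell 2.85-fold and 1.94-fold and the acetyl-CoA synthetase ACSS2 3.26-fold.

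Of 74 nuclear-encoded subunits of the respiratory chain, 30 fell and 6 rose, also adjusted over the list alone (median -0.17, camera adjusted p = 3.08e-05; adjusted p = 0.0714 with an estimated correlation). NDUFB9 fell 2.10-fold, ATP5MC1 1.82-fold and ATP5MC3 1.79-fold. Of 22 glycolysis genes, 9 fell and 2 rose, also adjusted over the list alone (median -0.14, camera adjusted p = 0.0269; adjusted p = 0.155 with an estimated correlation). That call was also lost with quantile normalization (median -0.18, adjusted p = 0.171; 0.0174 to 0.171 over all alternatives run with the preset correlation). The hexokinase HK2 and the enolase ENO2 rose 2.64-fold and 1.97-fold, and the aldolase ALDOC fell 2.65-fold. Of 20 hypoxia-inducible genes, 8 rose and 4 fell, also adjusted over the list alone, and the list was not shifted by camera (adjusted p = 0.489). The direction given by that test was upward, as was the mean log2 difference (0.33), while the median was -0.02. The angiogenic factor VEGFA rose 4.61-fold, and DDIT4 and STC2, which are also on the ATF4 list, rose 4.36-fold and 3.57-fold. Of 16 regulators of mitochondrial biogenesis, 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.726, direction downward; mean 0.01, median -0.04). TFB1M rose 1.28-fold, SIRT1 1.22-fold and PPRC1 1.21-fold. The list of mitochondrially encoded genes had 0 members in the table and was not tested.

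Heat shock proteins of the cytosol and mitochondria fell while the chaperones of the endoplasmic reticulum rose. Of 17 heat shock genes, 13 fell and 0 rose (14 and 1 adjusted over the list alone; median -0.48, camera adjusted p = 8.01e-07; adjusted p = 0.0544 with an estimated correlation). HSPA8, the constitutive cytosolic chaperone, fell 2.64-fold from 1345 ± 4.80 to 510.0 ± 15.6 FPKM (adjusted p = 6.74e-06), and the mitochondrial HSPE1 fell 2.05-fold. HSPA1A fell 2.19-fold, from 4.87 ± 0.0507 to 2.22 ± 0.150 FPKM. HSPA1A has a near-identical copy, and HSPE1 has a read-through partner. All 7 metallothionein and zinc export genes changed, 6 higher and 1 lower, also adjusted over the list alone (median 0.88, camera adjusted p = 0.00966; adjusted p = 0.155 with an estimated correlation). The metal-binding proteins MT1F, MT1M and MT2A rose 2.82-fold, 2.27-fold and 1.92-fold, and these too are near-identical to each other. Of 22 NRF2 targets, 7 fell and 6 rose, also adjusted over the list alone (camera adjusted p = 0.552; direction downward, median -0.07, mean 0.02). The cystine transporter SLC7A11, which is also on the ATF4 list, rose 2.75-fold, OSGIN1 2.52-fold and MAFG 1.93-fold. Of 5 AhR targets, 1 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.687). This was CYP1B1, which rose 1.37-fold.

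**Figure D3:**
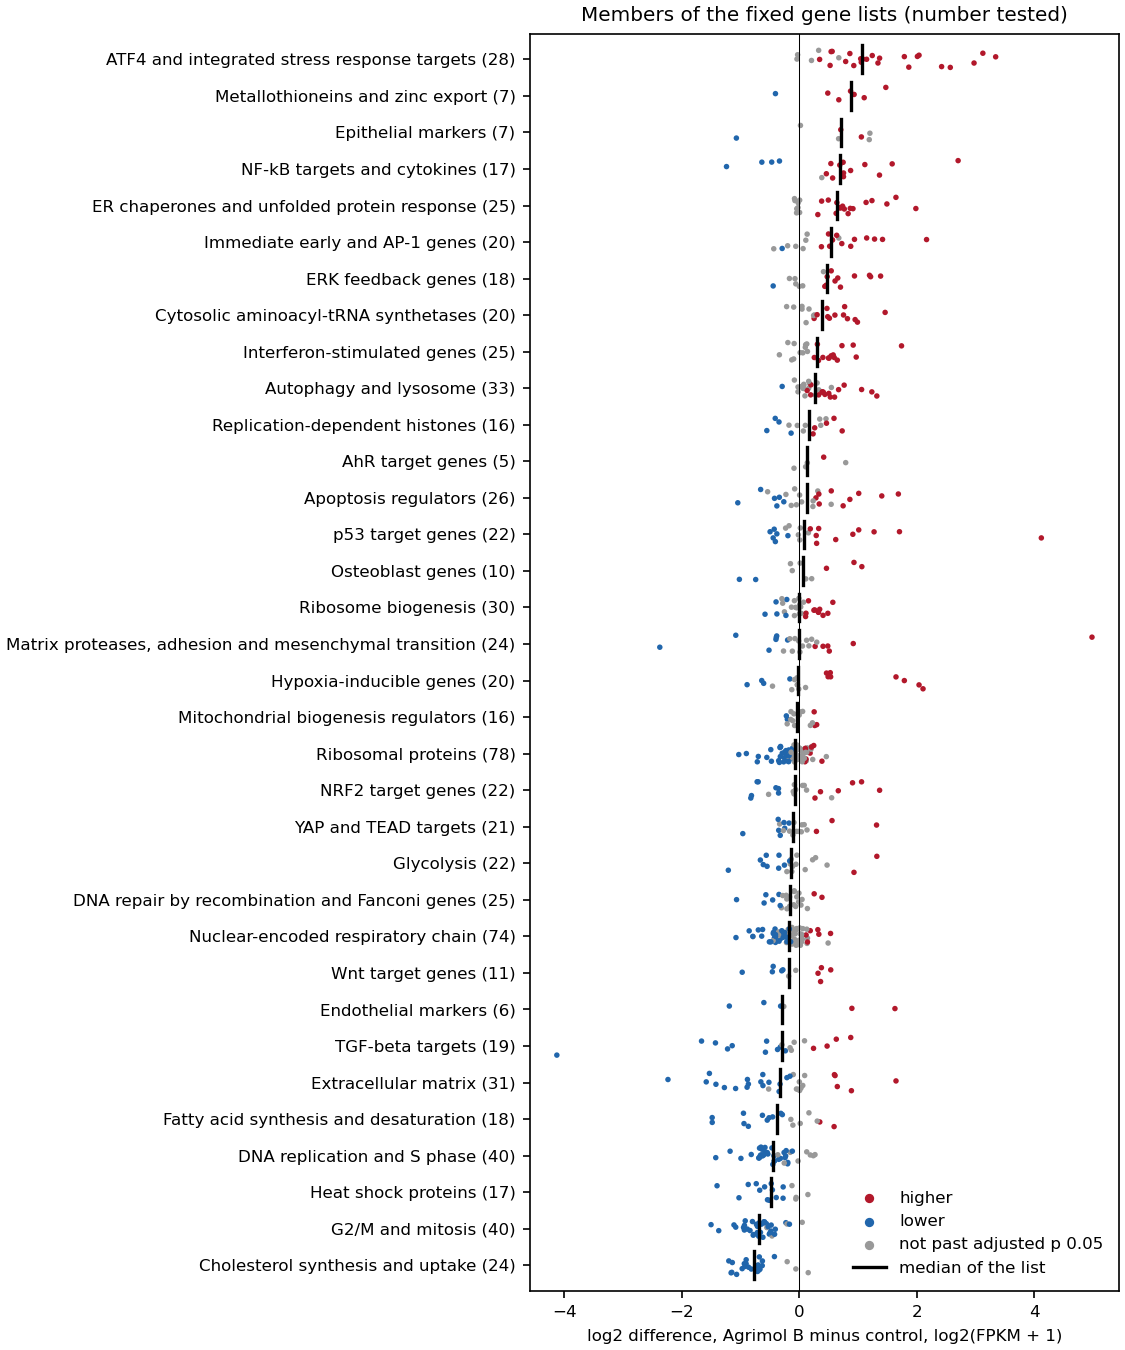
Each point is a tested member of a fixed list, placed by its log2 difference between Agrimol B and control libraries (log2(FPKM + 1)); red and blue mark members past adjusted p 0.05, black bars mark list medians, and lists are ordered by median. The ATF4 list has the highest median (1.07) and the cholesterol list the lowest (-0.76).

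Of 22 p53 targets, 10 rose and 6 fell, also adjusted over the list alone, and the list was not shifted by camera (adjusted p = 0.489; median 0.09). GDF15 rose 29.1-fold, the growth arrest gene GADD45A 3.33-fold to 133 ± 17.9 FPKM and the death receptor TNFRSF10B 2.50-fold. Of 26 apoptosis regulators, 9 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.726; median 0.14). HRK, which promotes apoptosis, rose 3.72-fold and CASP6, an executioner caspase, fell 2.46-fold. BCL2L2, which opposes apoptosis, stood at 8.58 ± 5.09 FPKM in control and 21.1 ± 0.659 FPKM in Agrimol B libraries (adjusted p = 0.0485). It shares sequence with a read-through gene, BCL2L2-PABPN1, which was chosen after its values were seen. That gene fell (log2 difference -1.75, adjusted p = 0.0052), and a shift of reads between them was not tested. The call of BCL2L2 was lost under most alternatives (adjusted p 0.000669 to 0.111). Its log2 difference of 1.41 became 0.82 without control replicate 2. Of 33 autophagy and lysosome genes, 16 rose and 1 fell, also adjusted over the list alone (median 0.28, camera adjusted p = 0.00440; adjusted p = 0.0857 with an estimated correlation). WIPI1 and MAP1LC3B, which act in autophagosome formation, rose 2.64-fold and 2.10-fold. The lysosomal protease CTSB rose 2.30-fold from 34.6 ± 20.5 to 79.7 ± 3.20 FPKM, and its log2 difference of 1.32 became 1.76 without control replicate 3, which stood at 58.3 FPKM against 23.6 and 22.0 FPKM in the other control libraries. This call was lost when any library except control replicate 3 was left out (adjusted p 0.0573 to 0.0685; 0.000203 to 0.0685 over all alternatives).

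Cytokine and early response genes rose. Of 17 NF-kB targets and cytokines, 12 rose and 4 fell, also adjusted over the list alone (median 0.69, camera adjusted p = 0.0115; adjusted p = 0.293 with an estimated correlation). CXCL8 rose 10.3-fold to 14.7 ± 0.892 FPKM, and CXCL2 and IL6 rose from 0.566 ± 0.159 and 0.365 ± 0.133 to 3.68 ± 0.0137 and 2.52 ± 0.326 FPKM. Of 25 interferon-stimulated genes, 14 rose and 0 fell, also adjusted over the list alone (median 0.31, camera adjusted p = 0.0240; adjusted p = 0.563 with an estimated correlation). The call was also lost without Agrimol B replicate 3 (adjusted p = 0.0582) and with a filter of 5 FPKM (adjusted p = 0.245). Over all alternatives run with the preset correlation, camera's adjusted p ran from 0.00941 to 0.245. IFIT2 rose 4.23-fold, OASL 3.15-fold and STAT2 2.09-fold. Of 20 immediate early and AP-1 genes, 12 rose and 1 fell, also adjusted over the list alone (median 0.54, camera adjusted p = 0.00283; adjusted p = 0.155 with an estimated correlation). The transcription factors KLF4, KLF2 and EGR1 rose 6.47-fold, 3.41-fold and 4.32-fold. Of 18 feedback genes of the ERK pathway, 11 rose and 1 fell (12 and 2 adjusted over the list alone; median 0.47, camera adjusted p = 0.0212; adjusted p = 0.293 with an estimated correlation). ETV5 rose 2.82-fold, PHLDA1 2.58-fold and ETV4 2.42-fold.

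Matrix genes and TGF-beta targets fell more often than they rose. Of 19 TGF-beta targets, 10 fell and 4 rose (11 and 4 adjusted over the list alone; median -0.29, camera adjusted p = 0.00894; adjusted p = 0.117 with an estimated correlation). Besides ACTA2, the actin-binding calponin CNN1 fell 3.44-fold and the inhibitory SMAD6 3.78-fold. Of 31 extracellular matrix genes, 17 fell and 5 rose, also adjusted over the list alone (median -0.33, camera adjusted p = 0.00157; adjusted p = 0.339 with an estimated correlation). COL3A1 and COL11A1 fell 4.89-fold and 3.44-fold, while LOX, which cross-links collagen, rose 3.34-fold. Of 24 genes of matrix proteases, adhesion and mesenchymal transition, 7 fell and 6 rose, also adjusted over the list alone (camera adjusted p = 0.495; direction downward, median 0.003, mean 0.11). MMP1 rose 40.8-fold, and S100A4 and the protease inhibitor TIMP3 fell 5.44-fold and 2.21-fold. Of 21 YAP and TEAD targets, 7 fell and 3 rose, also adjusted over the list alone (median -0.11, camera adjusted p = 0.159). NT5E and ANKRD1 rose 2.88-fold and 1.49-fold, and TGFB2 fell 2.45-fold. Of 11 Wnt targets, 5 fell and 4 rose, also adjusted over the list alone (median -0.18, camera adjusted p = 0.370). TNFRSF19 and AXIN2 fell 2.84-fold and 1.86-fold, and LEF1 rose 1.55-fold. Of 10 osteoblast genes, 3 rose and 2 fell, also adjusted over the list alone (median 0.07, camera adjusted p = 0.783). BMP2 and SPP1 rose 2.87-fold and 2.18-fold, and the alkaline phosphatase ALPL, a marker of bone-forming cells, fell 2.15-fold.

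Of 78 ribosomal proteins, 28 fell and 8 rose, also adjusted over the list alone (median -0.06, camera adjusted p = 0.00289; adjusted p = 0.563 with an estimated correlation). With quantile normalization, however, the median was 0.08 and the call was lost (camera adjusted p = 0.257; 0.000207 to 0.257 over all alternatives run with the preset correlation). RPS15, RPS26 and RPS10 fell 2.04-fold, 1.87-fold and 1.64-fold. RPS10 has a read-through partner, and many ribosomal protein genes have processed pseudogenes. Of 30 ribosome biogenesis genes, 11 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.883; direction downward, median 0.005, mean 0.02). RRP12 and PES1 rose 1.52-fold and 1.41-fold and UTP20 fell 1.53-fold.

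Markers of other cell types moved in both directions. Of 7 tested epithelial markers, 2 rose and 1 fell, also adjusted over the list alone (median 0.71, camera adjusted p = 0.495). CLDN3 was at 16.1 ± 1.89 FPKM and ESRP1 at 1.89 ± 0.0454 FPKM after rises of 2.24-fold and 2.44-fold, and ELF3 fell 4.07-fold to 0.539 ± 0.3 FPKM. Of 6 endothelial markers, 2 rose and 3 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.428; median -0.29, mean 0.03, direction downward). ROBO4 rose from 0.380 ± 0.0970 to 3.28 ± 0.402 FPKM and TIE1 from 0.508 ± 0.191 to 1.80 ± 0.262 FPKM, and TEK fell 3.85-fold. Of the leukocyte markers, 2 reached the filter, too few for a list test: CD68 rose 2.13-fold and CD14 fell from 1.44 ± 0.330 to 0.588 ± 0.191 FPKM.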

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

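The counts, named genes and lists were recomputed under every alternative. Removal of length and GC trends and of scattered and read-through genes was chosen after seeing the data. Changed genes numbered 4735 (filter of 5 FPKM) to 6882 (no filter) against 6311, and 5512 to 5731 with a library left out. Genes higher made up 58.8% of the calls, 49.2% with median-ratio scaling (3067 higher, 3164 lower) and 50.1% with quantile normalization. Genes changed at least 2-fold rose from 491 to 833 with a pseudocount of 0.1, which by construction shrinks low genes less, and lay at 503 to 516 with a library left out. Shifted lists fell from 20 to 0 with an estimated correlation, which replaces the preset correlation. This setting also tests each list on the 4 residual degrees of freedom of the libraries. In the heat shock, fatty acid, synthetase, TGF-beta, glycolysis and autophagy lists the estimated correlation (-0.0507 to 7.6e-05) was below the preset 0.01. A higher correlation within these lists therefore does not account for their lost calls. For the other called lists these effects were not separated. Shifted lists numbered 18 to 20 with the preset correlation with a library left out. All 117 named genes kept their direction in every alternative that tested them. BCL2L2, CTSB and HIST1H4C lost the call without some libraries, and BCL2L2 and HIST1H4C also elsewhere. For some lists not called in the main test, the direction given by the test turned, while the median often kept its sign. Medians under those alternatives are given, and the cause was not tested. Without a filter these were the histones (0.039), osteoblast genes (-0.007) and ribosome biogenesis (0.005). With a filter of 5 FPKM these were the histones (-0.137) and osteoblast genes (0.065). With fry these were NRF2 targets (-0.07), mitochondrial biogenesis (-0.038) and ribosome biogenesis (0.005). With quantile normalization this was ribosome biogenesis (-0.01), together with the ribosomal proteins (0.084), which had been called. The direction of the apoptosis regulators turned without Agrimol B replicate 1, with medians of -0.036 to 0.184 over the libraries left out. With the replicate number as a block, 5776 genes changed, 492 of them at least 2-fold, 20 lists were shifted, and no call of a named gene or list was lost. Deviations of same-numbered libraries correlated at 0.037, -0.006 and -0.015, and those of differently numbered libraries at -0.066 to 0.069. No effect shared by same-numbered libraries was therefore visible. Whether they shared a culture or a day is not given in the labels and cannot be decided from these values. Depth in reads is unknown, which leaves the counting error of genes with low values open.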

Other observations

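The 4 further lists, the explanations tested on the actin list except the Arp2/3 and length tests, those on the p53 and NRF2 lists, the tests of few reads and of read-through genes, the counts of splits, and the bound of 0.5 on the SD were chosen only after results had been seen. So were the genes named here that the report does not name.

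Genes of transport between the endoplasmic reticulum and the Golgi apparatus, a list written after GOLGA2, YIPF2 and YIF1A were seen among the larger rises, were mostly higher with Agrimol B. Of 55 genes, 38 rose and 1 fell, with a median log2 difference of 0.69. GOLGA2, a structural protein of the Golgi, rose from 18.1 ± 0.423 to 81.6 ± 1.52 FPKM, YIF1A from 105.0 ± 7.32 to 355.0 ± 3.90 FPKM, and the coat protein COPA from 44.0 ± 6.05 to 105.8 ± 3.76 FPKM (SD, n = 3 libraries per group). Among the 47 members not seen before the list was written, 32 rose and 1 fell (median 0.68).

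Tubulins moved the other way. Of 12 tubulin genes, 8 fell and 0 rose (median -0.83). TUBB fell from 1125 ± 10.02 to 586.6 ± 9.83 FPKM and TUBB4B from 450.1 ± 5.59 to 245.1 ± 10.2 FPKM. The median was -0.54 without control replicate 1, and 9 of the 12 had been seen before the list was written; of the other 3, 2 fell and 0 rose (median -0.39). Tubulin genes are near-identical in parts of their sequence, so the values of single members are uncertain.

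Actin and contractile genes fell together. Of 31 tested genes that the transcription factors SRF and MRTF are known to control, 24 fell and 2 rose (median -0.81, quartiles -1.31 and -0.41; among 16 members not seen before, 9 fell and 2 rose, with a median of -0.48). Under the other scaling that left the median of the 31 genes closest to 0, it was -0.867. The median-ratio factors of the libraries, 0.9725 to 1.0271, were too close to 1 for scaling by them to undo such a fall. The rescaled median therefore does not test a difference in scaling. The factors show only that, by that measure, the libraries differed little in scale over the tested genes as a whole. Length or GC content is argued against by a median of -0.817 once trends with them were removed. The 16 members not seen before were not examined separately under these settings. A fall of abundant transcripts in general is argued against by the median of -0.089 in the 300 most abundant other genes, and a fall of all actin cytoskeleton genes by the median of -0.114 in 29 Arp2/3, capping and cofilin-related genes (-0.18 with median-ratio scaling, -0.053 without control replicate 3). ACTA2, CNN1 and TAGLN are on both the actin list and the list of TGF-beta targets, so the falls of those lists are not fully separate results. Reads shared among the near-identical actins were not tested, and neither was the activity of SRF or MRTF.

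Members of the p53 and NRF2 lists rose with the ATF4 list, among them GDF15, GADD45A and SLC7A11. Whether p53 activation accounts for its list cannot be decided from these counts, since 10 of its 22 members rose and 6 fell. CDKN1A, a standard p53 target, rose 1.27-fold (6.26 ± 0.242 to 7.94 ± 0.785 FPKM, n = 3 per group), and MDM2 was at 10.9 ± 1.58 and 9.41 ± 3.08 FPKM. The same holds for NRF2 activation, with 6 rises and 7 falls among 22 members.

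In 251 of 12143 tested genes (2.07%), replicates lay far apart (SD over 0.5 on the log2 scale), and 9 of these were called. B2M, for instance, stood at 76.3, 292.8 and 288.9 FPKM in the control and at 53.2, 258.3 and 185.7 FPKM in the Agrimol B libraries. The number of annotated isoforms did not set these genes apart, since its median equalled that of expression-matched genes (ratio of medians 1.0, GENCODE release 29). How the authors' program divided reads among isoforms is not given, so that division stays open. Few reads stay open: the share of such genes at 100 FPKM or more was 0.66 times that between 1 and 2 FPKM (95% interval 0.31 to 1.39), but the pseudocount narrows the spread of low genes. Overlap with a gene on the same strand was more frequent than in matched genes (odds ratio 2.5, 95% interval 1.93 to 3.25; 56.3% against 34.0%), and read-through genes and their parents had 2.06 times the SD of matched genes, so division of reads between overlapping genes may account for part of the pattern. B2M, which overlaps no gene on its strand, and the other scattered genes without an overlap stay open, and no biological explanation was tested.

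Of the 10 splits of the 6 libraries into groups of 3, 1, the real one, gave as many changed genes (6311; highest other 1), genes higher (3713; highest other 0), genes lower (2598; highest other 1), genes changed at least 2-fold (491; highest other 1) and shifted lists (20; highest other 15, lowest other 7). With 10 splits no share under 0.05 can be reached.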
